A study of Mus musculus with 4 samples.

How the data were processed

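The series profiled dimethylation of histone H3 at lysine K36 (H3K36me2) by chromatin immunoprecipitation and sequencing (ChIP-seq) in cultured mesenchymal stem cells (MSCs) from mouse bone marrow. Per the labels, 1 ChIP library came from cells given 1 µM melatonin for 24 hours and 1 from untreated cells, and each had its own input library without antibody. Libraries were made by tagmentation and sequenced on an Illumina instrument, per the labels' protocols. The input libraries entered the peak calls only, and their own tag counts outside peaks were not analysed here. The labels give no replicate, so no p-value between the conditions was computed.

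The 2 peak lists were made with HOMER findPeaks in histone style, per the file headers, separately for each ChIP library against its matched input, with no pooling. Per the file headers, windows of 1000 bp needed a tag count with a Poisson p of 0.001 (at least 18 tags in the melatonin library and 17 in the untreated library), a fold over input of 4 and a Poisson p over input of 1e-04. Windows were stitched into regions of variable length, and the local background filter was switched off. The submitters' processing notes list BWA 0.7.13, Picard 1.126 and MACS2 2.1.0, while the file headers name HOMER and not MACS2. The HOMER version was not given in the sources used here.

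The deposited columns hold several units. The normalized tag count is a signal of ChIP tags per 10000000 total tags, per the file headers. The ChIP and input tag columns are also deposited as a signal, in steps of 0.5 tags before scaling, with the deeper library scaled down to the shallower one. The findPeaks score is the authors' tag score of a region, per the file headers. The fold over input is the authors' ratio of scaled ChIP to input tags, and the p-value over input is the authors' Poisson p without adjustment. The region size in bp and the clonal ratio were deposited too, and the latter was not used. Scores, folds and p-values were used only to describe, rank or filter peaks within a list.

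The processing notes name the mouse build mm39, but the deposited coordinates do not belong to it. The last peaks on chromosomes 3 and 7 end at 159805034 and 145328623, beyond the ends of those chromosomes in mm39. The share of peak midpoints inside protein-coding genes of the GRCm38.p6 RefSeq gene table had its minimum at a shift of 0 kb in both lists. The minimum lay within 20 kb of a 0 shift on 19 of 20 chromosomes, X being the exception. Coordinates were therefore read as GRCm38. That table gives no strand and no exons, so promoters, exons and introns were not separated and flanks were taken on both sides of a gene. A genome sequence was not used here, so repeats and assembly gaps were not considered.

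Overlap meant 1 bp or more. In the main setting, each share was set against 1000 random placements of the same peaks, with width and chromosome kept. Peaks were assigned in the order protein-coding gene body, 2 kb flank of one, body of another gene, and intergenic. A protein-coding gene (21887 tested) had a peak when one overlapped its body or the 2 kb on either side, so a peak could count for neighbouring genes. The 16 gene lists were fixed at the same stage as the naming rule, and every symbol matched the table. The number of members with a peak was placed as a percentile among 10000 random lists of the same size matched on gene length in 20 bins. Intervals are 95% Wilson intervals for shares, exact Poisson intervals for counts and exact binomial intervals for ratios of counts. They cover counting error only, and reads without molecular identifiers are not independent molecules.

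Genes are named by a rule fixed beforehand. Nsd2, Runx2, Sp7, Bglap, Alpl and Col1a1 are always named. Added are the 10 genes with the highest fold at a peak without overlap in the other list, per list, and the 10 shared genes highest in mean fold percentile, leaving out predicted genes. Each gene list gives up to 4 members with a peak in one library and up to 2 with a peak in both, by fold. For 1 gene that this rule would name, the result is not reported here.

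Alternatives set before the data were examined were an equal number of peaks per list, other overlap rules, gene bodies alone and 10 length bins. A q-value threshold, promoter windows from a transcription start and a repeat filter were planned but not run, since q-values, strand and sequence were lacking. A p of 1e-05, a fold of 6, wider flanks, shifted placements and matching within chromosomes were chosen after seeing the files. Both lists hold only chromosomes 1 to 19 and X, so the planned restriction to chromosomes removed nothing. On simulated data with 500 planted shared peaks among 7699, the overlap in excess of placement came to 497 ± 8.87 (SD over 20 runs). The simulated peaks were spread evenly, without the regional clustering of the real peaks. The simulation therefore checks the counting only, and excess over such placement does not count shared sites in the real lists. Of 200 random lists of 30 genes simulated without an effect, 4% fell outside the central 95%, against 53.5% of lists drawn with 5 times the weight on genes with a peak in the melatonin library alone. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.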

Results

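H3K36me2 was mapped in bone marrow MSCs, the stromal progenitors of bone, fat and cartilage cells, with and without melatonin, the pineal hormone. H3K36me2 is a histone mark written by enzymes such as NSD2, which the study's title links to bone-forming cells and to senescent MSCs. The comparison asked where the mark was called in each of the 2 conditions. The melatonin library held 14180076.5 tags and the untreated library 13198427.5, as the peak finder counted them. Each condition had 1 ChIP library, so every difference given here is between these 2 libraries, without a replicate check, and a peak missing from a list does not show that the mark was absent.

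Both libraries gave a small set of short regions. The melatonin list held 7699 peaks (95% Poisson interval 7528 to 7873) over 8.39 Mb, and the untreated list held 8361 peaks (8183 to 8542) over 9.13 Mb. The peaks contained 1.12% of the tags in the melatonin library and 1.24% in the untreated library. Of the melatonin peaks, 79.2% had the smallest possible width of 1000 bp, as did 79.6% of the untreated peaks. The widest regions measured 3064 bp and 4345 bp. The authors' fold over input had a median of 5.11 in the melatonin list and 4.87 in the untreated list, just above the required 4. Within the peaks, input tags had a median of 3 per kb in the melatonin list, against 6.17 expected genome-wide, and 3.5 per kb in the untreated list, against 6.6.

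Peak density varied far more between chromosomes than between the libraries. Chromosome 10 held 6.28 peaks per Mb with melatonin and 6.69 without, and chromosome 13 held 5.92 and 7.48. Chromosome 7 held 0.585 and 0.557 per Mb, chromosome 16 held 0.969 and 0.989, and the X chromosome held 0.211 in each list. Across the 20 chromosomes, the 2 lists' densities gave Pearson's r = 0.98 (permutation p = 1e-05, adjusted p = 5e-05 over 5 relations) and Spearman's rho = 0.96 (permutation p = 1e-05, adjusted p = 5e-05), the smallest p that the permutations can give. Without the 2 chromosomes farthest from the median, r was 0.98. The ratio of melatonin to untreated peaks was 0.921 over all chromosomes. It was lower on chromosome 13, at 0.791 (exact 95% interval 0.715 to 0.875), and on chromosome 3, at 0.807 (0.725 to 0.897). It was higher on chromosome 6, at 1.13 (0.986 to 1.3), and on chromosome 11, at 1.1 (0.94 to 1.28). These were the only chromosomes whose intervals excluded the overall ratio, by counting error alone. The intervals treat peaks as independent, although peaks clustered. On chromosome 13, the 1 Mb windows from 5000001, 16000001 and 75000001 held 36, 17 and 13 peaks with melatonin and 72, 52 and 41 without. These windows were picked for their low ratio, so they do not test whether the chromosome's ratio came from a few regions.

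**Figure D1:**
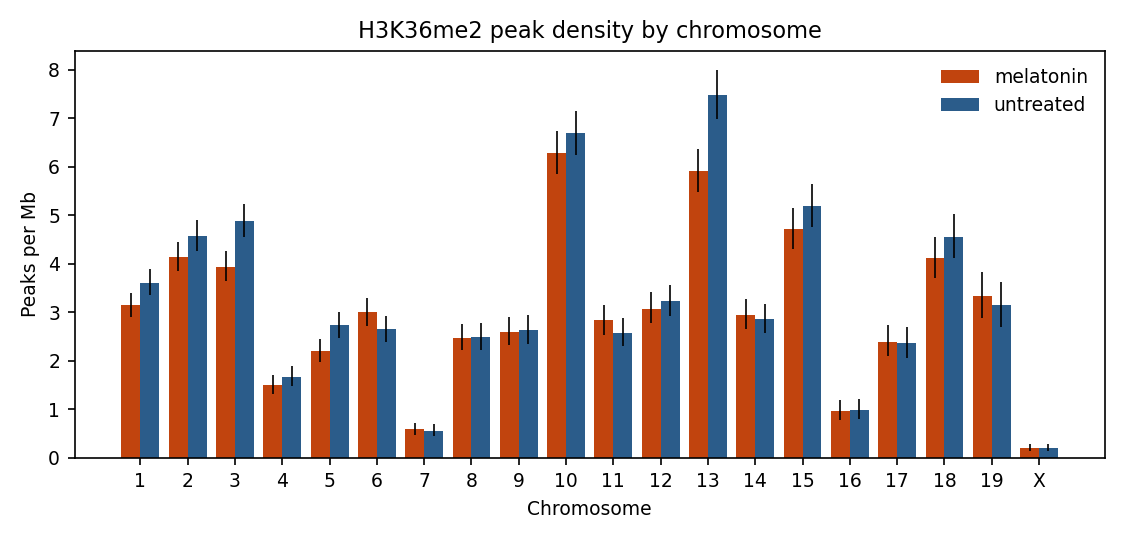
Bars give H3K36me2 peaks per Mb on each chromosome in the melatonin and the untreated library, and the lines are 95% Poisson intervals. Both libraries were highest on chromosomes 10 and 13 and lowest on the X chromosome, with 0.211 peaks per Mb in each.

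The peaks of both libraries lay outside protein-coding genes more often than placement by chance gave. In the melatonin list, 29.3% of peaks (95% Wilson interval 28.3 to 30.3) overlapped a protein-coding gene body, against a mean of 40.7% and a lowest value of 38.8% over 1000 random placements. In the untreated list the share was 28% (27 to 28.9), against a mean of 40.4% and a lowest value of 38.5%. Intergenic peaks made up 55.2% of the melatonin list and 57.4% of the untreated list, above all placements, whose means were 48.2% and 48.4%. Bodies of other genes, such as long noncoding RNAs and pseudogenes, held 13.9% and 13.2%, against means of 8.84% and 8.85%. The 2 kb flanks of protein-coding genes held 1.61% and 1.46%, against means of 2.35% and 2.31%. Flanks of 1 kb held 0.662% and 0.478%, against 1.23% and 1.21%. Flanks of 5 kb held 4.84% and 4.22%, against 5.2% and 5.19%, so the shortfall was small there with melatonin. The median distance to the nearest protein-coding gene was 25.4 kb with melatonin and 33.9 kb without, where 100 placements gave mean medians of 10.9 kb and 11.1 kb. Placements were not limited to sites with input low enough to pass the fold filter. Whether that filter shaped these shares and distances was not tested.

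**Figure D2:**
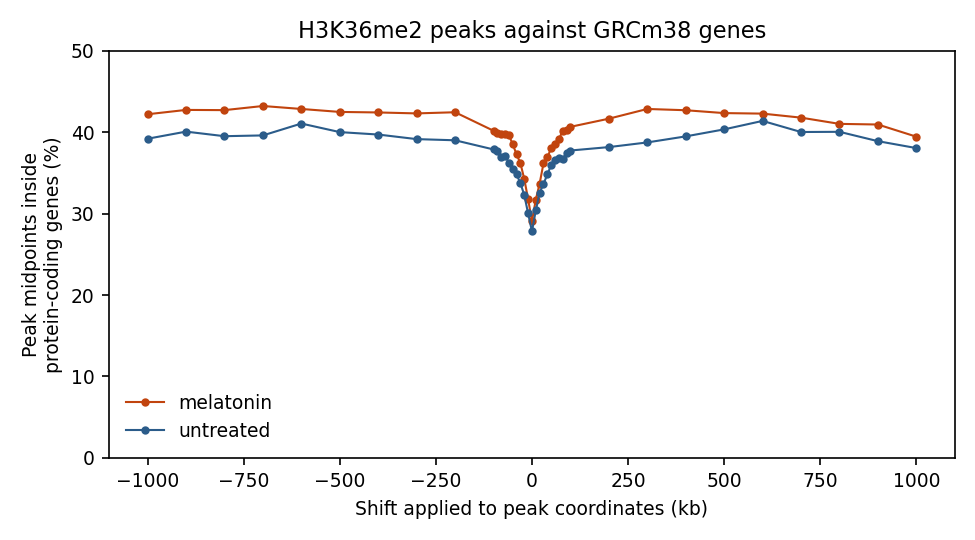
The vertical axis gives the percentage of peak midpoints inside GRCm38 protein-coding genes, and the horizontal axis the shift in kb applied to every peak. Both libraries had their lowest share, 29.1% and 27.8%, at a shift of 0, and lay between 37.7% and 43.2% at shifts of 100 kb or more.

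Few individual peaks were called in both libraries. Of the melatonin peaks, 471 (6.12%, Wilson interval 5.6 to 6.68) overlapped an untreated peak, and 468 of the untreated peaks (5.6%, 5.12 to 6.11) overlapped a melatonin peak. Random placement on the same chromosome gave a mean of 69.5 and a maximum of 99 overlapping melatonin peaks, so the observed number was 6.77 times that mean. Placement that moved each peak by 0.1 to 1 Mb, which keeps regional density, gave a mean of 149 and a maximum of 183. Against it the observed number was 3.17 times the mean, and 3.16 times for untreated peaks. The shared sequence came to 0.293 Mb, or 3.49% of the melatonin and 3.21% of the untreated peak length. Shared and unshared peaks differed little in the authors' fold within a list, with medians of 4.97 and 5.13 in the melatonin list and 4.84 and 4.89 in the untreated list. With each list cut into 10 equal parts by p, the part with the lowest p overlapped in 7.41% of cases in the melatonin list (Wilson interval 5.76 to 9.48) and 8.01% in the untreated list (6.36 to 10.05). The part with the highest p overlapped in 5.06% (3.73 to 6.85) and 4.78% (3.53 to 6.44). Ordered by ChIP tags, the overlap fell from 10.01% (8.09 to 12.34) in the strongest part to 4.42% (3.18 to 6.11) in the weakest in the melatonin list, and from 10.29% (8.41 to 12.53) to 3.46% (2.42 to 4.93) in the untreated list. Ordered by fold, the strongest part overlapped in 4.55% (3.29 to 6.26) and the weakest in 6.23% (4.73 to 8.17) in the melatonin list. In the untreated list these were 4.43% (3.23 to 6.04) and 6.09% (4.66 to 7.92), so the intervals overlapped in both lists. Between these ends the overlap by p or by fold did not change steadily. Counted from the strongest, it was highest in part 9 by p (7.66%) and part 8 by fold (9.22%) in the melatonin list. The ChIP tags were counted over the whole region, so wider regions tend to rank higher by tags, and width was not matched.

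**Figure D3:**
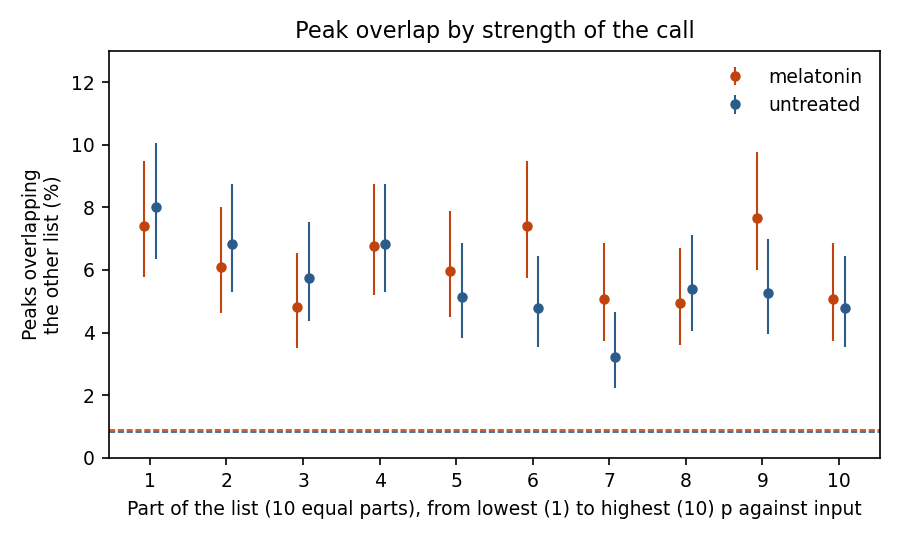
Points give the percentage of peaks that overlap the other library's list, with 95% Wilson intervals, in 10 equal parts of each list ordered by p against input; dashed lines are the means of random placement. No part exceeded 8.01%, and each lay above its list's mean of placement anywhere on the chromosome, 0.903% or 0.836%. Placements shifted by 0.1 to 1 Mb, not drawn, had means of 1.93% and 1.77%.

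Shared sites were ranked by mean fold percentile only where they lay in or beside protein-coding genes that were not predicted ones. The 10 highest genes are given here, and shared sites elsewhere were not ranked. The first was Dnm3, which encodes a dynamin and had overlapping peaks on chromosome 1 at 162227120 to 162228604 with melatonin (fold over input 12.6) and 162227964 to 162229215 without (7.21). Esr1, the estrogen receptor alpha gene, had overlapping peaks on chromosome 10 at 4808482 to 4810345 with melatonin (fold 6.43) and 4809242 to 4810242 without (5.77), among 13 and 5 peaks in the gene. The other 8 genes of this group were Lekr1, Atp8b5, Armc2, Kcnj16, Dock10, Chn2, Lipk and Prim2, and all but the Lipk pair, which lay just outside the gene, fell inside the gene.

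Among peaks of the melatonin list without an untreated counterpart, the highest folds in named genes were at Samd12 (44.4), Ctnnd2, a delta catenin (39.1), Angpt1, the angiopoietin ligand (38.3), Gria2, a glutamate receptor subunit (36.5), and Tnfsf15 (36.5). Usp43, Bbs9, Mblac2, Palld and Bank1 completed the 10, with folds from 32.2 to 34.8. In the untreated list they were at Zfpm2, a GATA cofactor (46.1), Emp1 (44.9), Gtdc1 (44.9), Plxdc2 (44.9) and Inpp4b (43.6). Ncam2, Arhgap24, Stxbp6, BC052040 and Ncoa1 followed, with folds from 23.1 to 38.5. All of these high folds rested on at most 0.8 input tags. Samd12, Ctnnd2, Angpt1, Bbs9, Palld and Bank1 of the melatonin group also held untreated peaks elsewhere in the gene, as Zfpm2, Gtdc1, Inpp4b, Arhgap24, BC052040 and Ncoa1 of the untreated group held melatonin peaks.

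Of 21887 protein-coding genes, 1299 (5.94%) had a melatonin peak in the body or the 2 kb flanks and 1250 (5.71%) had an untreated peak. Both libraries marked 602 genes, where independent sets of matched gene length would share 270. That expectation was not matched on chromosome or region, so it does not allow for the peak density that the libraries share. A peak was called with melatonin alone in 697 genes and without melatonin alone in 648. Genes with a peak were long, with a median of 198 kb for those in both lists, 66.8 kb for melatonin alone and 75.5 kb for untreated alone, against 17.2 kb for all protein-coding genes. Longer genes span more sequence where a peak can fall, and these medians were not set against random placement.

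The osteoblast list had a peak in about as many genes as random lists of matched length. Runx2, the transcription factor that commits cells to the osteoblast lineage (chromosome 17, 44495987 to 44814797), had 1 peak with melatonin at 44536102 to 44537505 (fold 7.1, p = 1.18e-11 in the authors' list). Without melatonin it had 2 peaks, at 44761394 to 44762394 (fold 4.27) and 44769574 to 44770574 (fold 17.1), and none overlapped across the libraries. Sp7 (osterix), Bglap (osteocalcin), Alpl (alkaline phosphatase) and Col1a1 (the main bone collagen chain) had no peak in either list. The nearest peaks lay 309 kb with melatonin and 336 kb without from Sp7, 1389 and 1399 kb from Bglap, 1375 and 1353 kb from Alpl, and 783 and 296 kb from Col1a1. Nsd2 itself (chromosome 5, 33820676 to 33897966) had no peak in either list, with the nearest at 123 kb with melatonin and 72.1 kb without. Of 27 osteoblast genes, 2 had a peak in each library. Fgf2, a growth factor, had one with melatonin alone (fold 5.36), and Bmpr1a, a bone morphogenetic protein receptor, without it alone (fold 4.44). The counts lay at the 51st and 53.7th percentiles of random length-matched lists, and the difference of 0 at the 47.3rd. With 10 kb on both sides the difference was -2, at the 10.7th percentile, and among the 3849 peaks of lowest p in each list it was -1, at the 18.1th.

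The senescence and secretory list stood farthest from random lists in its difference. Of its 27 members, 0 had a melatonin peak and 3 had an untreated peak, a difference of -3 at the 0.44th percentile of random lists. These were the matrix metalloproteinase genes Mmp3 (fold 5.13) and Mmp13 (fold 4.98), both on chromosome 9, and Nfkb1 (fold 4.3), an NF-kappaB subunit gene whose peak lay just outside the gene. It was the only one of 16 lists whose difference fell outside the central 95% of random lists, where 0.8 lists would do so by chance. The difference was 0, at the 44.8th percentile, among peaks with a fold of at least 6, and -1, at the 11.1th percentile, among the 3849 peaks of lowest p in each list. With 10 kb on both sides it was -3, at the 2.515th percentile, inside the central 95%. Mmp13 (7272514 to 7283333) and Mmp3 (7445822 to 7455975) lie close together. Random lists were not matched on how near members lie to each other, so the percentiles do not allow for this.

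Among 19 stromal progenitor genes, 1 had a melatonin peak and 3 had an untreated peak (difference -2, percentile 4.82). Lepr, the leptin receptor gene that marks marrow stromal cells, had a peak without melatonin alone (fold 7.26), as did Kitl, the stem cell factor gene (fold 9.61), while Nt5e, an ecto-nucleotidase gene used as an MSC marker, had peaks in both. With 10 kb on both sides of the gene the difference was -6, at the 0.015th percentile, and at a fold of at least 6 it was -3, at the 0.04th. Among the 3849 peaks of lowest p in each list it was -2, at the 2.03rd percentile, and with random lists matched within chromosomes it was -2, at the 7.83rd.

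In the adipocyte list 2 of 17 genes had a peak in both libraries, and in the chondrocyte list 1 of 14. Pparg, the main transcription factor of fat cells, had 2 peaks with melatonin and 4 without, and Cd36, a fatty acid transporter gene, had 2 and 1. Zfp423, a preadipocyte factor, had a peak with melatonin alone (fold 4.02), so that 3 and 2 of 17 adipocyte genes had a peak, at percentiles 75.7 and 49. The adipocyte difference of 1 changed sign with the setting: it was 4, at the 99.4th percentile, with 10 kb on both sides, 0, at the 49th, among the 3849 peaks of lowest p in each list, and -1, at the 16.1th, at a fold of at least 6. Sox5, a cartilage transcription factor gene, had 5 and 10 peaks and was the only marked member of 14 chondrocyte genes, at percentiles 29.2 and 31.2. At a fold of at least 6 it was marked without melatonin alone (difference -1, percentile 12.9).

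The melatonin and clock list had peaks in 5 of 24 members with melatonin and 4 without, at percentiles 98.6 and 94.9, which fell to 81.7 among the 3849 melatonin peaks of lowest p and to 69.2 among untreated peaks with a fold of at least 6. Both melatonin receptor genes, Mtnr1a and Mtnr1b, lacked a peak. Cry1, a clock repressor, had overlapping peaks in the 2 libraries (folds 4.47 and 4.56), and Rora, a nuclear receptor of the clock loop, had 3 and 2 peaks. Arntl, which encodes BMAL1, had peaks with melatonin alone (best fold 8.04), as did Npas2, which is named outside the rule after its values were seen. Hlf and Rorb had peaks without melatonin alone (best folds 6.84 and 5). The list's difference of 1 lay at the 75.2nd percentile.

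The H3K36 enzyme and reader list, which includes Nsd1, Nsd2, Nsd3, Setd2 and Kdm2a, had 0 of 19 members with a peak in either library, at percentiles 2.83 and 2.98, or 16.7 and 21.4 at a fold of at least 6. As fixed, this list also holds Lgr5, a receptor gene of neither kind. The Wnt, BMP and TGF-beta list had 1 of 30 with melatonin, Acvr1 (fold 8.04), an activin receptor gene, and 0 without, at percentiles 10.3 and 1.9. Over the alternatives these ran from 4.51 to 71.05 with melatonin and from 0.82 to 18 without. None of 20 cell cycle genes or 18 housekeeping genes had a peak in either library, where random lists averaged 0.843 and 0.26 with melatonin.

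Genes that mark other marrow or unrelated cell types also carried peaks. Of 17 macrophage and myeloid genes, Ptprc (fold 5.22) and Csf1r (fold 4.6) had a peak with melatonin alone and Mrc1 (fold 7.26) without it alone, at percentiles 88.5 and 61. The Ptprc and Csf1r peaks lay just outside the genes, so for gene bodies alone the melatonin count was 0, at the 21.8th percentile, and the difference of 1 became -1, at the 14.6th. At a fold of at least 6 it was also -1, at the 7.38th. Of 13 endothelial genes, Vwf (fold 7.83) and Pecam1 (best fold 4.47) were marked with melatonin alone, Flt1 (fold 6.25) without it alone and Emcn in both, at percentiles 89.2 and 70.9, and the difference of 1 became 0 among the 3849 peaks of lowest p in each list and at a fold of at least 6. None of 19 lymphoid and erythroid genes had a peak. Of 20 neuronal genes, 7 had a peak in each library, at percentiles 84.6 and 86.3, with ranges of 60.7 to 97.555 and 40.8 to 97.525 over the alternatives. Both upper ends came from matching in 5 length bins within each chromosome, which is coarser in length than the 20 bins. Dlg2 and Gad2 were marked in both, Gria2 with melatonin alone and Nrxn3 without it alone. Olfactory receptor genes, which MSCs are not known to use, had a peak in 1 of 1106 members with melatonin, Olfr427, and in 0 without, at percentiles 0.235 and 1.42, which reached 10.4 for gene bodies alone and 31.1 at a fold of at least 6. Of 394 genes with Zfp symbols, 18 had a peak with melatonin and 9 without, at percentiles 61.3 and 2.02, and the difference of 9 lay at the 96.6th percentile. It was -1, at the 33.4th percentile, among the 3849 peaks of lowest p in each list, and 1, at the 44.2nd, at a fold of at least 6, where the untreated percentile was 58.4. Zfp608 (fold 17.4) and Zfp469 (best fold 8.04) were among those marked with melatonin alone, Zfp618 (best fold 9.74) and Zfp638 (fold 9.23) among those without it alone, and Zfp704 and Zfp474 had peaks in both.

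**Figure D4:**
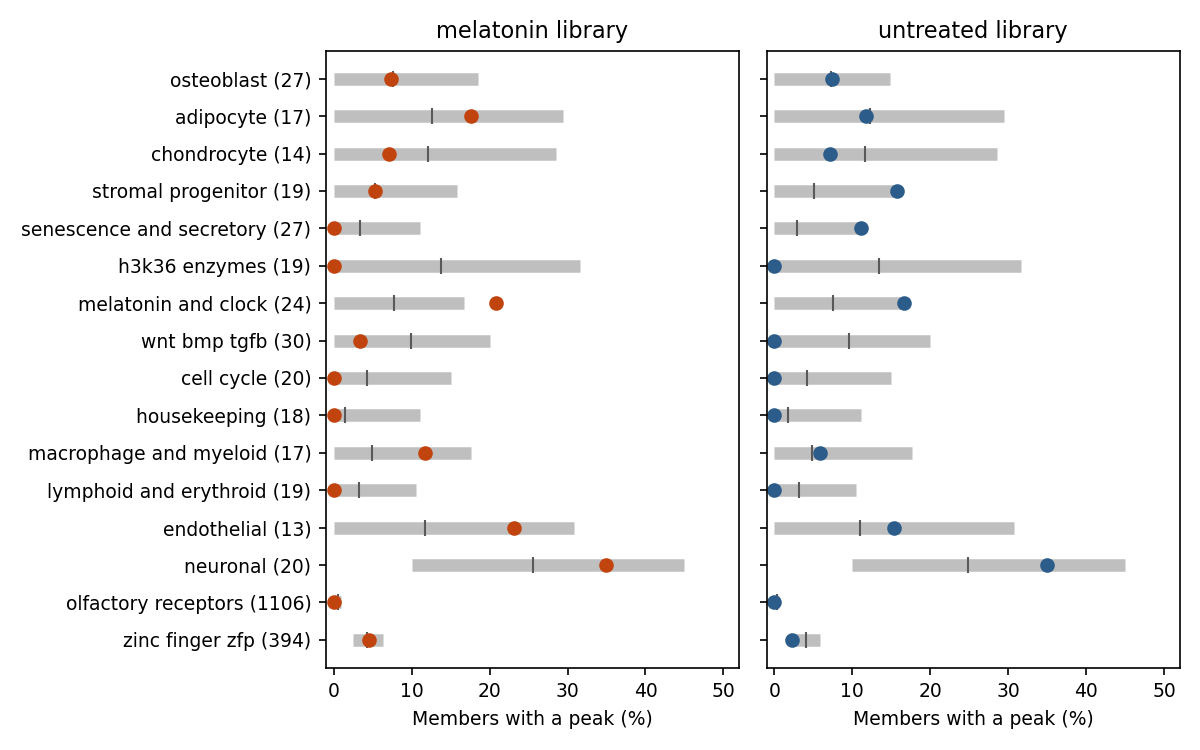
Points give the percentage of each gene list's members with a peak in the melatonin library (left) and the untreated library (right), with the number of members in brackets. Grey bars span the central 95% of 10000 random lists matched on gene length and ticks mark their mean; the senescence and secretory list stood at 0% and 11.1%.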

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

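No paired analysis was possible because each condition has 1 ChIP library, and for the same reason no replicate could be left out. The thresholds of p and fold, the 10 kb flanks, the shifted placements and the matching within chromosomes were chosen after seeing the data. In all 7 alternatives for overlap, the share of overlapping peaks stayed above every placement run, from 0.993% to 9.38% in the melatonin list and from 1.14% to 8.72% in the untreated list. Its lowest values came at a fold of at least 6 in both lists. At a fold of at least 6 in one list against all peaks of the other, it was 5.27% and 5.26%. The alternatives for overlap used 200 placements, except 50 where 50% of a peak had to be covered and 1000 for shifted placements. In all 4 alternatives for gene bodies, their share stayed below placement, from 28.4% to 30.6% and from 27.1% to 28.7%. Stricter thresholds shortened the lists by construction. Taking the same number by lowest p left 3849 peaks in each list, over 4.51 Mb with melatonin and 4.58 Mb without, and a fold of at least 6 left 2317 peaks over 2.54 Mb and 2017 peaks over 2.2 Mb. Genes marked in both lists then fell from 602 to 285 and 159. Genes marked without melatonin alone numbered 427 and 303, and genes marked with melatonin alone numbered 412 at a fold of at least 6. With 10 kb on both sides of a gene, 1139 genes were marked with melatonin alone and 1023 without it alone. Under that setting 2 gene lists, adipocyte and stromal progenitor, differed by more than the central 95% of random lists, against 1 (senescence and secretory) as reported. With the same number of peaks per list and at a fold of at least 6 it was the stromal progenitor list alone, and in the other 4 settings the senescence and secretory list, so which list stood apart depended on the setting and the cause was not tested. A median peak in the melatonin list rested on a score of 19 tags where 18 were required.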

Other observations

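The tests of neighbouring peaks within 10 kb, of gene density in matched windows and of shifted placements, and the window and gene counts of the first paragraphs, were chosen after the results they follow from were seen.

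The peaks of both libraries gathered in the same megabase-sized regions. Across 2641 windows of 1 Mb, the peak counts of the 2 libraries had Spearman's rho = 0.8 over windows (median 0.78 within chromosomes), though windows are not independent replicates. The window on chromosome 2 from 45000001 to 46000000, whose only protein-coding gene is Zeb2, a transcription factor gene, held 53 peaks with melatonin and 44 without. The window on chromosome 10 from 96000001 to 97000000, with Btg1, Eea1 and Gm46240, held 50 and 42. The window on chromosome 15 from 62000001 to 63000000, without a protein-coding gene, held 38 and 43. Among genes, Lrmda had 30 and 24 peaks, Hdac9, a histone deacetylase gene, had 22 and 21, Pard3b had 16 and 31, and Pde4d, a phosphodiesterase gene, had 15 and 17.

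Some of these regions held fewer peaks with melatonin. The window on chromosome 13 from 16000001 to 17000000, with Inhba, the activin A subunit gene, and Sugct, held 17 peaks with melatonin and 52 without (ratio 0.327, exact 95% interval 0.177 to 0.575). The window on chromosome 13 from 5000001 to 6000000, with Klf6, held 36 and 72 (0.5, 0.326 to 0.756). The window on chromosome 10 from 16000001 to 17000000, without a protein-coding gene, held 33 and 67 (0.493, 0.314 to 0.758). In the other direction, the window on chromosome 1 from 106000001 to 107000000, which contains the survival gene Bcl2, held 17 and 6 (2.83, 1.07 to 8.78). Of 184 windows with at least 20 peaks, 14 (7.61%) lay outside the central 95% of a binomial split at the overall ratio, where 5% would do so by chance, 11 of them lower and 3 higher with melatonin. Among genes, Pard3b had a ratio of 0.516 (0.264 to 0.973), Prkg1 held 7 and 19 peaks (0.368, 0.131 to 0.915) and Atp8b4 1 and 8 (0.125, 0.0028 to 0.932). In the other direction Atrnl1 held 9 and 1 (9, 1.25 to 394), Tg 10 and 2 (5, 1.07 to 46.9) and Esr1 13 and 5 (2.6, 0.87 to 9.31). Of these 6 genes, only the intervals of Prkg1, Atrnl1 and Tg excluded the overall ratio of 0.921. These windows and genes were picked for their difference, and the intervals cover counting error alone.

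Few peaks overlapped between the lists, although the regions were shared. Regional density shared only at scales above 0.1 Mb, without shared sites, is argued against. The observed overlap of melatonin peaks was 2.57 times the highest of 1000 placements that moved each peak by 0.1 to 1 Mb. Density shared at finer scales would pass that test too, so the test does not establish shared sites. Broad enriched regions called in different windows of 1000 bp are a candidate explanation: 26.3% of unshared melatonin peaks and 25% of unshared untreated peaks had a peak of the other list within 10 kb, where such shifts gave at most 14.4% and 14.3%, so the lower ratio was 1.75. This test replaced one within 100 kb against placement anywhere on the chromosome, which the shared regional density alone would have passed. It was set up with the 10 kb shares known, and separate sites lying close together would pass it too. Calls near the thresholds stay open, because the rankings disagree. With each list cut into 10 parts, the overlap in the strongest part over that in the weakest was 1.46 and 1.68 by p, between the bounds of 1.2 and 2 set for p beforehand, 2.27 and 2.97 by ChIP tags, and 0.73 in both lists by fold. The ranking by ChIP tags favours wider regions, which can meet the 1 bp overlap rule more easily. An effect of melatonin on single sites stays open and untested, for lack of a second library per condition.

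Peaks per Mb differed more than 10-fold between chromosomes in both lists. Gene density as the whole cause is argued against: in windows with 0 to 5 protein-coding genes, chromosome 10 still held 11.1 times as many peaks as chromosome 7 with melatonin (bootstrap 95% interval 5.94 to 25.2) and 12.4 times as many without. This test took the place of a rank correlation set beforehand, whose result left gene density undecided (rho = -0.181 and -0.269 between genes and peaks per Mb over 20 chromosomes), and the 2 chromosomes were picked for their difference. Extra copies or coverage of some chromosomes, which one genome-wide tag threshold would turn into more peaks, may contribute and could not be decided. Input tags per kb within peaks had rho = -0.217 and 0.467 with peak density over 20 chromosomes, and the fold filter holds those input tags in a narrow range. Without the 2 chromosomes farthest from the median, rho was 0.0246 with melatonin and 0.164 without. A difference in the mark between chromosomes stays open as well, and input coverage outside peaks was not analysed here.

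Input tags within peaks lay below the genome average in over 99% of peaks of each list. The calling rule itself requires this at the threshold: a window with 18 tags passes a 4-fold filter only with at most 3.92 scaled input tags in the melatonin list, where 6.17 are expected. Whether the low input was a chance dip of each input library or a property of the site could not be decided. Input tags of the 2 libraries had rho = -0.0133 over 471 shared peaks (bootstrap 95% interval -0.109 to 0.0913), but the filter narrowed their range: the variance was 1.54 around a mean of 3.61 tags with melatonin and 2.47 around 4.21 without, below counting noise. How strong a site property this comparison would have detected was not tested.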
